A study of Xenopus tropicalis with 20 samples.

How the data were processed

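Liver RNA of 20 mature Xenopus tropicalis (western clawed frog) females was sequenced, 5 from each of 4 groups. The groups were first-generation (F1) and second-generation (F2) offspring of founder (F0) frogs kept with a mixture of benzo[a]pyrene, a polycyclic aromatic hydrocarbon, and triclosan, an antimicrobial agent, and F1 and F2 control offspring. Per the labels' protocols the F0 frogs were exposed at 50 ng/L from tadpole to mature adult, while the F1 and F2 females were not exposed. The labels do not say whether that concentration was for each compound or for the sum. RNA came from 15 mg of liver per biological replicate, libraries were made with the TruSeq Stranded mRNA kit, and reads were 75 bp long, per the labels' protocols. Per the series' design text the control reads had been deposited with an earlier series, so the control and mixture libraries could differ in when they were made or sequenced. No date or run is given in the sources used here, and such a batch cannot be told apart from the group.

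Each library had a table of FPKM (fragments scaled by transcript length and by the number of mapped fragments) per gene, with lower and upper confidence limits in the same unit, which the authors made with Trimmomatic 0.32.1, HISAT2 and Cufflinks 0.0.7, per the submitters' processing notes. The authors also deposited 2 Cuffdiff 0.0.7 tables, 1 per generation, whose columns hold a mean FPKM per group, a log2 fold change, a test score, a p-value and a q-value, per the file headers. Those tables were used only where the text says the authors' deposited table. Each library table had 20442 lines, of which 70 carried no gene name. These held 0.000624% to 0.00856% of the summed FPKM and were left out. The genome build is not given in the sources used here. Of the 20372 named genes, 20164 (99.0%) had the same start and end as in the reference gene table of the assembly UCB_Xtro_10.0, so coordinates below are those of the deposited tables, stated for that assembly and counted from 1. A total of 5131 genes carried only a LOC identifier. For 2 F1 mixture libraries, 9 and 13, the file name carried the number of the other, and each file was taken for the sample it was deposited under, which does not change the group.

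Cufflinks marks each estimate as sound or not. Values marked as having too much data (HIDATA, 5 genes) or a failed estimate (FAIL, 42 genes) are listed at 0 or unreliable, and were set to missing in those libraries. A gene needed at least 3 sound values in every group. Vitellogenin vtga2 and albumin alb, among the most abundant liver transcripts, were lost this way. Of the other genes meant to be named in any case, cyp1b1 and insr were under the level filter, and vtgb1 and fgf21 were not analysed here. A value of exactly 0 can also be a failed estimate, so genes at 0 in a whole group are said to be listed at 0, and no fold is given for them.

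The files hold no read counts. Taking the deposited FPKM limits as 2 Poisson SD on each side, they correspond to 7896840 to 16705912 fragments per library. This sum covers only genes marked sound with a lower limit above 0, so it is not the whole depth. Left out were vtga2 in 18 libraries and alb in 8, with sound alb values in 4 F1 control and 2 F1 mixture libraries. The group means ± SD (n = 5) were 10231655 ± 1541124 in F1 control, 15339430 ± 1344198 in F1 mixture, 12802219 ± 1314955 in F2 control and 12945765 ± 2042082 in F2 mixture. At an FPKM between 5 and 20 the median half-width of the deposited interval was 7.92% to 10.97% of the value. On that assumption it covers counting error only. Among genes marked sound, the 10 most abundant held 19.3% to 32.3% of the summed FPKM.

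FPKM values were divided by a scaling factor per library, the median over 6971 genes (FPKM of 1 or more in every library) of the ratio to the gene's geometric mean. The factors ran from 0.717 to 1.26. A pseudocount of 1 was added and log2 taken, so a fold change is on the log2(scaled FPKM + 1) scale and understates the change of genes with low values. Genes with a mean FPKM of 1 or more over the 20 libraries entered the test, 10228 genes. The test was limma 3.58.1 in R 4.3.3 with all 20 libraries in 1 model of 4 group means and a trend of the variance, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 3 contrasts were F1 mixture against F1 control, F2 mixture against F2 control, and the difference between those effects (F2 minus F1). Fold changes are given ± SE and levels as mean ± SD over 5 libraries. The extraction protocol speaks of biological replicates without naming the animals or clutches they came from, so sisters within a group cannot be excluded.

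Gene lists, 46 in all, were fixed before the data were examined, as were the tests, the first set of alternatives and the rule for named genes. Of these lists, 40 had at least 5 measured members. They were tested on 10193 genes with a value in every library by limma's camera with a preset correlation of 0.01, by camera with the correlation estimated from the data, and by fry, each adjusted over the 40 lists. A member counts as having risen or fallen at an adjusted p under 0.05 over all genes tested, and each count is also given adjusted over the list alone. The rule named the 8 largest fold changes in each direction among called genes with a symbol and a mean scaled FPKM of 5 or more in the higher group (the 3 smallest p in each direction where none was called), up to 4 members with the smallest p of each list described, a fixed set of genes in any case where measured, the 5 largest differences between the generations in each direction, and genes called in both generations, of which there were 0. Which lists are described in detail, and how many of their members, was chosen after the values were seen. Some genes that the rule named are not reported here. Values and calls of the authors' deposited tables stand apart and are named each time.

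Library numbers occur in both F2 groups, 1 to 5. Deviations from the group means correlated between F2 libraries of the same number at 0.385, 0.369, 0.154, 0.104 and 0.169 (numbers 1 to 5). The mean of 0.236 was the highest of the 120 possible pairings (exact permutation p = 0.00833, one-sided). The numbers were therefore taken to pair the F2 libraries, on evidence from the data and not from the labels, and F2 results were also fitted with the number as a block. The alternatives were another pseudocount, no filter and a stricter filter, no scaling, quantile normalization, a fit of the compared generation alone, limma's arrayWeights, the block, and leaving out each library in turn. Alternatives chosen only after seeing the data were keeping the FAIL values, the mean of the erythrocyte list as a covariate, removing each library's trend with transcript length, a threshold of 0.10, and the block in combination with the list tests, the length trend or the erythrocyte mean. Transcript length was inferred from the deposited limits for 10211 genes (99.8% of those tested).

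The tests were checked on simulated data. On 9950 genes drawn independently of each other from the library means and spreads, 200 changed genes were set in F2 mixture against F2 control. The changed genes were picked among those with higher levels only. Of those changed 1.5-fold, 13.4% were called, of those changed 2-fold 52.2%, and of those changed 4-fold 87.9%. There were 4 false calls among 9750 unchanged genes, and 0 calls in F1, where nothing was changed. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.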

Results

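The liver transcriptome was measured in 20 mature Xenopus tropicalis females, 5 in each of the groups F1 control, F1 mixture, F2 control and F2 mixture. The mixture females descend from founders kept with benzo[a]pyrene, which activates the aryl hydrocarbon receptor, and triclosan, and were themselves unexposed. The deposited limits of genes marked sound correspond to 7896840 to 16705912 fragments per library. By this measure F1 mixture libraries held more fragments (15339430 ± 1344198, SD, n = 5) than F1 control libraries (10231655 ± 1541124). The number of genes at an FPKM of 1 or more ran from 8474 to 10642 per library.

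The F1 comparison asked whether livers of first-generation daughters differed by the treatment of their parents. No gene passed the test: limma called 0 of 10228 genes, while 1306 had an unadjusted p under 0.05 and the authors' deposited table (Cuffdiff) marked 268 as significant. Of these 268, 118 were higher and 150 lower in the mixture group. A total of 230 were tested with limma and all 230 had the same sign there. The smallest p values among genes higher in the mixture group belonged to epha2, an ephrin receptor (chromosome 7, 131376390 to 131412012), at 3.07 ± 1.15 scaled FPKM in controls and 10.9 ± 4.61 in the mixture group (log2 fold change 1.52 ± 0.27, SE, adjusted p = 0.0655). Next came emilin1, an elastic fibre glycoprotein (1.42 ± 0.26, adjusted p = 0.0655), and prcp, a carboxypeptidase (1.04 ± 0.21, adjusted p = 0.0944). Among genes lower in the mixture group they belonged to flcn, the gene of folliculin (chromosome 9, 15783695 to 15791567), at 18.3 ± 5.90 and 5.70 ± 3.33 scaled FPKM (-1.62 ± 0.31, adjusted p = 0.0798). Next came uckl1, a uridine-cytidine kinase (-0.88 ± 0.17, adjusted p = 0.0798), and apoa5, an apolipoprotein (-1.67 ± 0.35, adjusted p = 0.111). The authors' deposited table marked epha2, emilin1, prcp, flcn and apoa5 as significant, and not uckl1.

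Glucose 6-phosphatase, the last enzyme of glucose release, has several copies on chromosome 10, between which reads can be split. In F1, g6pc.1 (21457994 to 21463115) stood at 233 ± 153 scaled FPKM in controls and 28.1 ± 15.2 in the mixture group (log2 fold change -2.86 ± 0.87, adjusted p = 0.238). The values of g6pc.2 were -1.86 ± 0.87 and of g6pc.3 -2.16 ± 0.99 (adjusted p = 0.385 and 0.378). The authors' deposited table marked all of g6pc.1, g6pc.2 and g6pc.3 as significant. In the gluconeogenesis list 0 of 23 measured members passed over all genes. Adjusted over the list alone 1 rose, ugp2, which makes UDP-glucose (0.93 ± 0.23), and 1 fell, g6pc.1. In the glycolysis list 0 of 26 passed, and 1 rose adjusted over the list alone. In the amino acid catabolism and urea cycle list 0 of 33 passed, and adjusted over the list alone 2 fell, nags (-2.40 ± 0.63) and asl (-1.26 ± 0.34), both urea cycle enzymes. In the vitellogenin and estrogen response list 0 of 6 passed, and 2 rose adjusted over the list alone, with ttr, transthyretin, at 1.81 ± 0.66 (adjusted p = 0.32 over all genes). The authors' deposited table marked ugp2, nags, asl and ttr as significant.

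Gene lists for protein synthesis, respiration and secretion lay higher in the F1 mixture group by camera with a preset correlation, although 0 of their members passed over all genes or adjusted over the list alone. All 62 measured ribosomal protein genes had a positive log2 fold change (median 0.65, adjusted p = 3.22e-14), with rps26 at 1.06 ± 0.43 and rpl10a at 0.98 ± 0.40. Of 51 nuclear genes of oxidative phosphorylation 49 were positive (median 0.58, adjusted p = 8.80e-14), with the ATP synthase genes atp5f1c at 0.91 ± 0.31 and atp5mc1 at 1.1 ± 0.39. The other lists were secreted liver proteins (31 of 35 positive, adjusted p = 5.73e-06, with serpinc1, antithrombin, at 1.20 ± 0.35), proteasome (31 of 35, 4.57e-05) and complement (25 of 25, 7.17e-05). Further ones were the tricarboxylic acid cycle (21 of 24, 0.00267, with mdh2 at 0.98 ± 0.36), the unfolded protein response (26 of 32, 0.00472) and the NRF2 oxidative stress response (18 of 21, 0.00923). The erythrocyte list moved with them (14 of 16, adjusted p = 0.0301, with the globin gene hba2 at 1.87 ± 0.74). Cholesterol synthesis and uptake lay lower, with 1 of 23 positive (median -0.53, adjusted p = 0.0140). For each of these 10 lists the adjusted p = 0.863 with an estimated correlation, which was 0.912 among ribosomal protein genes, and fry called 0 lists. The slope of log2 level on log2 transcript length was 0.058 ± 0.102 in F1 control and -0.011 ± 0.086 in F1 mixture libraries (mean ± SD, n = 5 each), with F1 control 3 at -0.093, F1 mixture 1 at 0.088 and F1 mixture 8 at 0.067. With the length trend removed 9 of the 10 lists passed camera, and the erythrocyte list did not (0.0984). After quantile normalization 7 passed, and the ribosomal protein (0.842), NRF2 (0.0734) and erythrocyte (0.271) lists did not. The cholesterol call ended without F1 mixture 1 (0.415) or 4 (0.429) or F1 control 1 (0.227), 3 (0.366) or 4 (0.277), and the NRF2 call without F1 mixture 9 (0.155). That of the unfolded protein response ended without F1 mixture 13 (0.166) or F1 control 2 (0.0919) or 6 (0.0660). The erythrocyte call ended without F1 mixture 4 (0.461), 9 (0.254) or 13 (0.0775) or F1 control 2 (0.114) or 3 (0.0765). For the other 30 lists the adjusted p with the preset correlation lay between 0.140 and 0.996.

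The F1 count changed with single libraries. It was 24 without F1 mixture 8, 21 without F1 control 3, 5 without F1 mixture 1 and 1 without F1 control 4 or 6. The weights of limma's arrayWeights were 0.447 for F1 mixture 1, 0.555 for F1 mixture 8 and 0.566 for F1 control 3, and with them 1129 genes were called (502 higher, 627 lower), with 28 of the named genes among them. Without F1 control 3 the adjusted p of emilin1 was 0.0124, of prcp 0.0230, of flcn 0.0242, of uckl1 0.0242 and of epha2 0.0434. Without F1 mixture 8 it was 0.0360 for emilin1, 0.0360 for uckl1 and 0.0426 for epha2, and without F1 mixture 1 it was 0.0406 for flcn. Quantile normalization gave 0.0436 for epha2, removal of the length trend 0.0268 for epha2, and FPKM without scaling 0.0468 for apoa5. Of the genes of the exposure response and growth, cyp1a1 stood at 0.14 ± 0.33, ahr at 0.16 ± 0.17 and igf1 at -0.01 ± 0.39 in F1 (adjusted p = 0.880, 0.683 and 0.996).

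**Figure D1:**
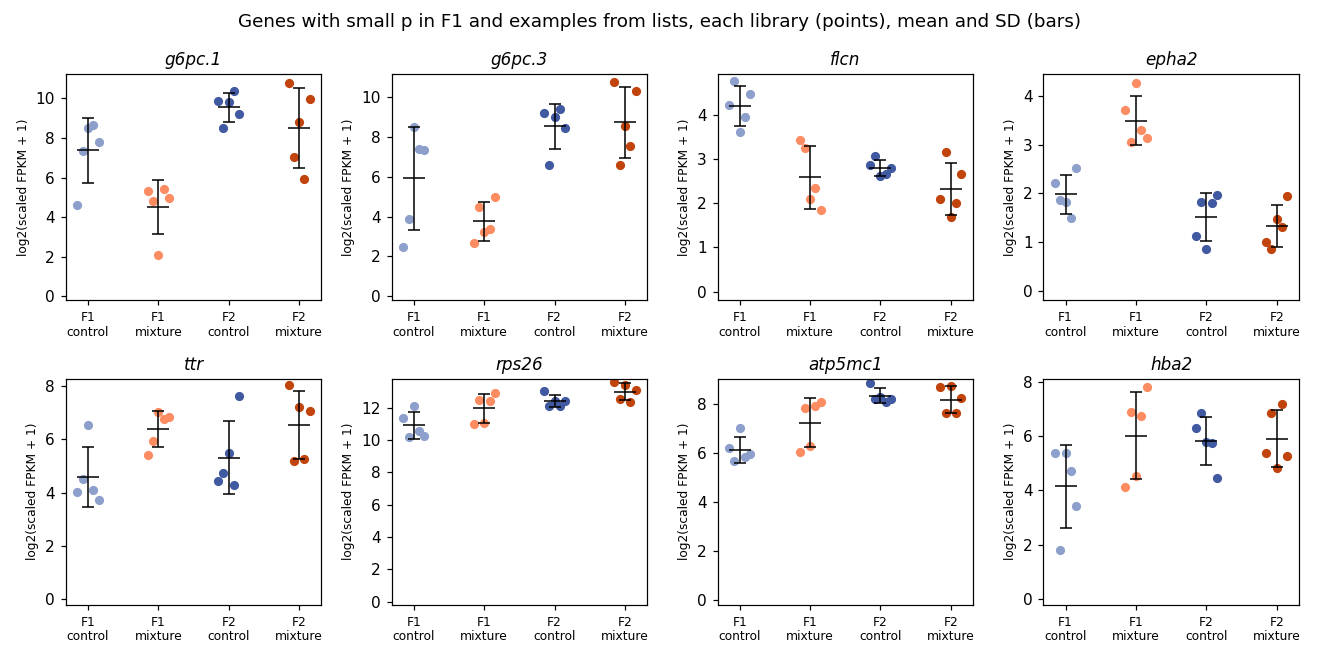
Level on the log2(scaled FPKM + 1) scale per library in the 4 groups for g6pc.1, g6pc.3, flcn, epha2, ttr, rps26, atp5mc1 and hba2 (points, 5 libraries a group) with the mean and SD of these log2 values (bars). In F1 the mean of g6pc.1 before log2 was 233 scaled FPKM in controls and 28.1 in the mixture group, with library values that spread widely.

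The F2 comparison asked the same of the second generation, and there the groups differed in many genes. A total of 2630 genes passed, 1151 higher and 1479 lower in F2 mixture livers, of which 801 differed over 2-fold (373 higher, 428 lower). Of the 2630, 2130 were also called between F2 and F1 control livers, and 318 between F2 and F1 mixture livers. Both contrasts share libraries with the F2 test. A rise or fall below is relative to F2 control livers, and for many genes it was these that differed from F1. The authors' deposited table marked 2204 genes as significant, and 1363 were called by both, all in the same direction. Of the called F2 genes named below, it did not mark ahr, idh3a, hsd17b11, atg12 and lamp1 as significant. Nor did it mark tf, for which it gave an F2 control mean of 0, or the 3 genes described below as listed at 0. Among the largest falls were apln, the gene of the peptide hormone apelin (chromosome 8, 52326973 to 52341115), from 20.4 ± 8.17 to 1.94 ± 1.25 scaled FPKM (-2.91 ± 0.30, adjusted p = 3.67e-06). Others were tmem97, a sterol-regulated membrane protein (-2.71 ± 0.36), sdc4, a heparan sulfate proteoglycan (-2.66 ± 0.43), and cyp8b1.1, a bile acid hydroxylase (-2.64 ± 0.57). They were followed by gm2a, a lysosomal ganglioside activator (-2.52 ± 0.26), and rfk, riboflavin kinase (-2.46 ± 0.36). The stearoyl-CoA desaturase gene scd fell (-2.64 ± 0.83, adjusted p = 0.0246). This call ended without F2 mixture 3 (0.0809), F2 mixture 4 (0.0646), F2 control 1 (0.0665) or F2 control 4 (0.0678), with F2 libraries alone in the fit (0.0599), and with the library number as a block and the erythrocyte mean as a covariate (0.102). The largest rises were in lrrc43 (2.62 ± 0.69) and snrnp70, a protein of the U1 spliceosome particle (chromosome 7, 113682407 to 113696367, 85.6 ± 17.9 to 483 ± 213 scaled FPKM, 2.33 ± 0.37, adjusted p = 0.000271). They were followed by uroc1, urocanase of histidine breakdown (2.28 ± 0.59), mab21l3 (2.23 ± 0.44) and rgp1 (2.20 ± 0.52). The rule also named ccdc152, rec114 and mitd1, listed at 0 in all 5 F2 control libraries, for which no fold is given. In F2 mixture libraries 1 to 5, ccdc152 stood at 34.3, 0, 21.1, 13.6 and 33.4 scaled FPKM, rec114 at 21.0, 0, 11.3, 15.9 and 16.5, and mitd1 at 0, 6.24, 7.31, 7.28 and 8.98. The authors' deposited table gave F2 control means of 10.6 for ccdc152, 1.37 for rec114 and 10.1 for mitd1 and marked none of the 3 as significant. The call of mitd1 ended without F2 mixture 4 (0.0507).

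Single genes of lipid metabolism and growth signalling fell in F2 mixture livers. Of all 10228 tested genes 1151 rose and 1479 fell, so some called members would be found in most lists. The counts per list, here and below, are to be read against that share. In the list of fatty acid oxidation and ketogenesis 13 of 30 measured members fell, 0 rose and 17 did not pass (14 fell adjusted over the list alone). These included bdh1, of ketone body metabolism (-1.45 ± 0.19), cpt2, of mitochondrial fatty acid import (-0.97 ± 0.20), and acadl, an acyl-CoA dehydrogenase (-0.88 ± 0.19). It was the 1 list that passed camera with the preset correlation (adjusted p = 0.00447), with adjusted p = 0.935 with an estimated correlation and 0.00356 by fry. With the library number as a block it had 0.00655 by camera with the preset correlation and 0.0303 by fry. Without F2 mixture 2 the camera p of the list was 0.0647 and 0 lists passed. In fatty acid and triglyceride synthesis 5 of 25 fell and 0 rose (4 fell adjusted over the list alone), among them me1, malic enzyme (-1.45 ± 0.25), and elovl1, a fatty acid elongase (-1.01 ± 0.19). The fatty acid synthase gene fasn stood at -0.73 ± 0.82 (adjusted p = 0.542). By camera the synthesis list had an adjusted p of 0.330. In the list of lipid droplets, lipoproteins and fatty acid uptake 2 of 24 fell and 0 rose, as adjusted over the list alone, and the list did not pass (camera 0.237, fry 0.113). These were mttp.1, which loads lipid onto lipoproteins, from 18.0 ± 4.11 to 3.47 ± 0.86 scaled FPKM (-2.08 ± 0.17, adjusted p = 5.80e-07), and apoe (-0.68 ± 0.20). In insulin and IGF signalling 2 of 31 rose and 5 fell (2 and 3 adjusted over the list alone), and the list did not pass (camera 0.897, fry 0.763). The growth factor gene igf1 (chromosome 3, 49174280 to 49237834) fell from 17.2 ± 16.4 to 1.70 ± 0.57 scaled FPKM (-2.33 ± 0.39, adjusted p = 0.000453). In F1 igf1 stood at 1.24 ± 0.30 in control and 1.29 ± 0.68 in mixture livers, so the F2 control level was the one that stood apart. The growth hormone receptor gene ghr fell (-1.13 ± 0.26, adjusted p = 0.00385, 0.0569 with the library number as a block, and 0.0523 with the block and the length trend removed), and sesn3, a sestrin, rose (1.23 ± 0.27). The IGF-binding protein gene igfbp1 stood at 11.7 ± 11 and 94.8 ± 112 scaled FPKM (2.25 ± 0.94, adjusted p = 0.0848, 0.00845 without F2 mixture 2, 0.0112 with arrayWeights and 0.0385 with the block and the erythrocyte mean as a covariate). The authors' deposited table marked igfbp1 as significant.

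**Figure D2:**
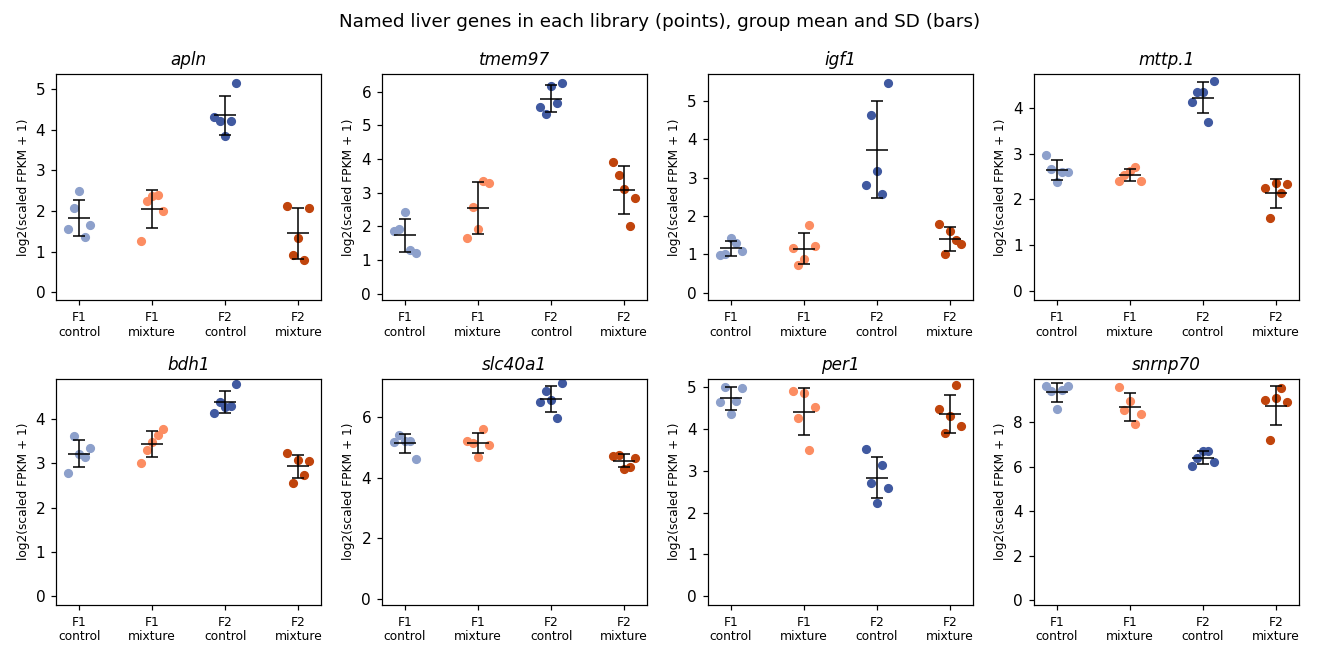
Level on the log2(scaled FPKM + 1) scale per library in the 4 groups for apln, tmem97, igf1, mttp.1, bdh1, slc40a1, per1 and snrnp70 (points, 5 libraries a group) with the mean and SD of these log2 values (bars). Before log2 the F2 control mean of apln was 20.4 scaled FPKM and the F2 mixture mean 1.94, while snrnp70 stood at 85.6 in F2 control and 483 in F2 mixture libraries. In F1 control and F1 mixture libraries apln stood at 2.70 and 3.31, and snrnp70 at 667 and 440.

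In the list of the aryl hydrocarbon receptor, which benzo[a]pyrene activates, and its targets, 4 of 8 members fell in F2 mixture livers and 0 rose, also adjusted over the list alone. The best-known target cyp1a1 fell from 95.5 ± 25.2 to 41.8 ± 17.7 scaled FPKM (-1.29 ± 0.33, adjusted p = 0.00719). The receptor gene ahr (-0.73 ± 0.17), cyp1d1 (-0.95 ± 0.26) and ugt1a1 (-0.77 ± 0.23) fell as well. The call of ugt1a1 ended without F2 control 3 (0.0642), F2 control 5 (0.0696) or F2 mixture 4 (0.0516) and with F2 libraries alone in the fit (0.0687). With the library number as a block and the erythrocyte mean as a covariate the calls of ugt1a1 (0.0655) and cyp1d1 (0.0653) ended. By fry the list had an adjusted p of 0.00131, and 0.0698 with the library number as a block, while camera gave 0.0975 and an adjusted p of 0.933 with an estimated correlation. In the NRF2 list 1 of 21 rose and 6 fell (1 and 7 adjusted over the list alone), with gclm, of glutathione synthesis, at -1.08 ± 0.25 and nqo1 at 0.23 ± 0.19 (adjusted p = 0.397). In steroid metabolism 4 of 15 fell and 0 rose, also adjusted over the list alone, among them hsd17b8 (-1.20 ± 0.17), the mineralocorticoid receptor gene nr3c2 (-0.68 ± 0.10) and hsd17b11 (-0.71 ± 0.21), whose call ended without F2 control 3 (0.0600) and with that block and covariate (0.0520). In the thyroid and retinoid list 2 of 20 rose and 4 fell, also adjusted over the list alone. Here the retinal reductase dhrs3 (-1.42 ± 0.25), the retinal dehydrogenase aldh1a1 (-1.46 ± 0.30) and the carotenoid cleavage enzyme bco2 (-1.02 ± 0.28) fell and the retinoid receptor gene rxra rose (0.69 ± 0.19, adjusted p = 0.0687 with that block and covariate). By fry the steroid list had an adjusted p of 0.00223 and the thyroid and retinoid list 8.85e-05, and with the library number as a block 0.0179 and 0.0303. By camera they had 0.0970 and 0.225, and an adjusted p of 0.933 each with an estimated correlation.

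Members of lists of central metabolism, iron handling, lysosomes and secreted proteins were also called, and none of these lists passed camera. In the tricarboxylic acid cycle 2 of 24 rose and 8 fell (2 and 10 adjusted over the list alone), with suclg2 (-1.01 ± 0.20), sucla2 (-0.85 ± 0.18), aco1 (-0.95 ± 0.18) and idh3a (-0.69 ± 0.15) fallen. In iron and heme 9 of 26 fell and 0 rose (9 fell and 1 rose adjusted over the list alone). The iron exporter ferroportin, slc40a1 (chromosome 9, 47793288 to 47812854), fell from 101 ± 29.4 to 22.8 ± 3.46 scaled FPKM (-2.06 ± 0.22, adjusted p = 6.22e-06). Also fallen were tf, transferrin (-1.27 ± 0.34), and hjv, hemojuvelin (-0.83 ± 0.22). In autophagy and lysosome 10 of 31 fell and 0 rose, also adjusted over the list alone, among them the protease genes ctsd (-1.46 ± 0.21) and ctsh (-1.21 ± 0.31), atg12 (-0.73 ± 0.16) and lamp1 (-0.87 ± 0.23), whose call ended with the library number as a block and the erythrocyte mean as a covariate (0.0582). By fry these lists had adjusted p values of 0.0264, 0.00635 and 0.0169, and with the library number as a block 0.0121, 0.0121 and 0.0439. By camera they had 0.0970 each, with an adjusted p of 0.935 with an estimated correlation. Of 35 secreted liver proteins 8 fell and 0 rose, also adjusted over the list alone (camera 0.0975, fry 0.277), with fgb, a fibrinogen chain (-2.0 ± 0.44), gc, the vitamin D-binding protein (-1.30 ± 0.33), and serpind1, heparin cofactor (-1.46 ± 0.37). In amino acid catabolism 1 of 33 rose and 7 fell, also adjusted over the list alone (camera 0.225, fry 0.277), with got2 (-1.0 ± 0.20) and mat1a (-1.77 ± 0.37) fallen. In the vitellogenin and estrogen response list 1 of 6 fell, ctsd, also adjusted over the list alone.

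Risen genes outnumbered fallen ones in the circadian and chromatin lists, neither of which passed camera. In the circadian list 6 of 16 rose and 0 fell (7 rose adjusted over the list alone), with per1 from 6.49 ± 2.65 to 20.3 ± 7.19 scaled FPKM (1.52 ± 0.28, adjusted p = 0.000887), arntl (1.23 ± 0.27), cry2 (1.41 ± 0.33) and per3 (1.20 ± 0.32). The list had an adjusted p of 0.0265 by fry (0.0303 with the library number as a block) and 0.0970 by camera, and an adjusted p of 0.935 with an estimated correlation. The time of day of sampling is not given in the sources used here. Among DNA methylation and chromatin modifiers 8 of 34 rose and 2 fell, also adjusted over the list alone (camera 0.0975, fry 0.217). The methyl-CpG-binding gene mbd1 (1.13 ± 0.18), the histone methyltransferase genes ezh1 (1.15 ± 0.25) and setdb1 (0.67 ± 0.16, adjusted p = 0.0791 without scaling) and the acetyltransferase gene ep300 (0.91 ± 0.20) rose. The maintenance DNA methyltransferase gene dnmt1 stood at 0.34 ± 0.16 (adjusted p = 0.129, 0.0254 after quantile normalization, and 0.0359 with the block and the length trend removed). Of 62 ribosomal protein genes 4 rose and 1 fell, with 0 adjusted over the list alone, rpl23 at 1.30 ± 0.34 and rpl7 at -1.47 ± 0.47. The call of rpl7 ended without F2 mixture 3 (0.0606), F2 mixture 4 (0.0927), F2 control 1 (0.0660) or F2 control 5 (0.0546). Camera gave the ribosomal list 0.0970, and 0.00266, higher in the mixture group, with the library number as a block. Fry gave it 0.179 with that block, so it did not pass there. With an estimated correlation the adjusted p of the lists lay between 0.933 and 0.935.

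The named genes of glucose release did not pass in F2, with g6pc.1 at -1.05 ± 0.87, g6pc.2 at 0.52 ± 0.87, g6pc.3 at 0.21 ± 0.99 and pck1 at 1.22 ± 0.87 (adjusted p = 0.394, 0.690, 0.895 and 0.316). In the whole list of gluconeogenesis and glycogen 1 of 23 members rose and 2 fell. The authors' deposited table marked pck1 as significant, as it did cyp7a1. The lipid regulators srebf1 (-0.40 ± 0.29), ppara (-0.18 ± 0.30), pparg (0.36 ± 0.31) and ppargc1a (0.32 ± 0.56) did not pass either. Nor did cpt1a (0.22 ± 0.34), ldlr (0.28 ± 0.47), cyp7a1 (-0.60 ± 0.68, adjusted p = 0.0471 with the block and the erythrocyte mean as a covariate), gck (-0.45 ± 0.53), irs2 (-0.32 ± 0.20), leprot (-0.44 ± 0.25) or the glucocorticoid receptor gene nr3c1 (-0.01 ± 0.18) pass. Without scaling the F2 count was 1961, of which 31.8% were higher against 43.8% with scaling, and the median over all genes was -0.10 against -0.038. Quantile normalization gave 51.0% (1380 higher, 1327 lower, median over all genes 0.011), and removal of the length trend 1474 higher and 1335 lower. For genes with a mean FPKM of 5 or more it was 1486 (878 higher, 608 lower). Reads of bdh1, acadl, idh3a, serpind1, ccdc152, rec114 and mitd1 are uncertain, since each overlaps another annotated gene and the use of strand in counting is not given in the sources used here.

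The test of the difference asked whether the mixture effect was the same in both generations. It called 2052 genes, 974 with a higher and 1078 with a lower effect in F2 than in F1, of which 1277 differed over 2-fold. The difference was not fitted with the library number as a block, so its calls leave the F2 pairing aside. Higher effects outnumbered lower ones at a mean FPKM of 5 or more (776 and 582), with the length trend removed (1172 and 1133), after quantile normalization (1105 and 1099) and without F1 mixture 1 (1298 and 1271). The difference (F2 minus F1, log2) was 3.93 ± 0.84 for uroc1 (chromosome 4, 132977433 to 132999424), whose level was 284 ± 156 in F1 control, 96.0 ± 73.6 in F1 mixture, 63.9 ± 63.9 in F2 control and 261 ± 135 in F2 mixture livers. It was 3.0 ± 0.53 for snrnp70 and 2.98 ± 0.65 for tubz1, a tubulin gene. In the other direction it was -3.78 ± 0.77 for slc51b, a bile acid exporter subunit (chromosome 3, 116314035 to 116320977), at 9.68 ± 8.69 and 51.4 ± 37.7 scaled FPKM in F1 control and mixture and 13.5 ± 9.51 and 5.04 ± 5.18 in F2. The proton channel gene otop2 (-3.72 ± 1.01), tmem97 (-3.53 ± 0.51), cyp8b1.1 (-3.40 ± 0.80) and pon2, a paraoxonase (-3.36 ± 0.49), followed. Of these slc51b, otop2 and pon2 overlap another annotated gene and are uncertain. The genes rec114 and mitd1, listed at 0 in all F2 control libraries, were called as well. The call of mitd1 (adjusted p = 0.0322) ended without F1 mixture 8 (0.0510) or 9 (0.0682), F1 control 4 (0.0581) or 6 (0.0556), or F2 mixture 3 (0.0540), 4 (0.0605) or 5 (0.0552), and with no filter (0.0583).

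Genes of secretion, respiration and lipid breakdown were among those with a lower effect in F2. Camera called 7 lists for the difference, all with a lower effect in F2: secreted liver proteins (11 of 35 lower, adjusted p = 0.00266, 12 adjusted over the list alone), oxidative phosphorylation (1 of 51 higher and 12 lower, 0.00266, the same counts adjusted over the list alone) and fatty acid oxidation (10 of 30 lower, 0.00436, 11 adjusted over the list alone). Further ones were the tricarboxylic acid cycle (10 of 24 lower, 0.00727, 1 higher and 13 lower adjusted over the list alone) and iron and heme (1 of 26 higher and 6 lower, 0.0216, 1 and 7 adjusted over the list alone). The last were NRF2 (4 of 21 lower, 0.0331, 1 higher and 6 lower adjusted over the list alone) and complement (1 of 25 lower, 0.0331, also adjusted over the list alone). With an estimated correlation 0 lists passed, at an adjusted p of 0.821 for fatty acid oxidation, the tricarboxylic acid cycle and iron and heme, and 0.884 for the others. By fry fatty acid oxidation (0.0157), the tricarboxylic acid cycle (0.0147) and iron and heme (0.0147) passed, and secreted proteins (0.132), oxidative phosphorylation (0.227), NRF2 (0.0860) and complement (0.227) did not. Fry also called the aryl hydrocarbon receptor (0.0147), steroid (0.0157) and thyroid and retinoid (0.000690) lists, lower in F2, at an adjusted p of 0.821 each with an estimated correlation. Without F2 mixture 2 camera called 4 lists, with secreted proteins (0.0846), NRF2 (0.0592) and complement (0.221) lost. The NRF2 call also ended without F1 mixture 4 (0.0533), 9 (0.103) or 13 (0.0562), F1 control 2 (0.0551), 4 (0.0511) or 6 (0.0564), F2 mixture 4 (0.0545) or F2 control 1 (0.101). The complement call ended after quantile normalization (0.107) and without F1 mixture 8 (0.0805) or 9 (0.0964), F1 control 1 (0.0805) or 4 (0.0855), or F2 control 1 (0.0915) or 5 (0.0743). Single differences were -1.97 ± 0.49 for serpinc1, -1.74 ± 0.32 for uqcrc2, a complex III subunit, 1.19 ± 0.34 for ndufv1 of complex I and -1.67 ± 0.27 for bdh1. Others were -1.38 ± 0.26 for sucla2, -2.07 ± 0.32 for slc40a1, -0.91 ± 0.23 for nfe2l2, which encodes NRF2, -1.61 ± 0.45 for cat.2, a catalase, and -1.92 ± 0.53 for c6.1, a complement gene. In igf1 it was -2.32 ± 0.56, in arntl 1.85 ± 0.39, in per1 1.84 ± 0.40, in mbd1 1.39 ± 0.25 and in ezh1 1.56 ± 0.35.

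No gene was called in both generations: limma gave 0, as the F1 comparison called 0 (1306 genes with an unadjusted p under 0.05 in F1 and 3921 in F2, and 268 and 2204 significant genes in the authors' deposited tables). Across the 10228 genes, which are not independent replicates, the fold changes of the generations correlated at r = -0.219 (Spearman's rho = -0.283), with a jackknife SE over libraries of 0.154. Of the 2630 genes called in F2, 747 (28.4%) had the same sign in F1.

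**Figure D3:**
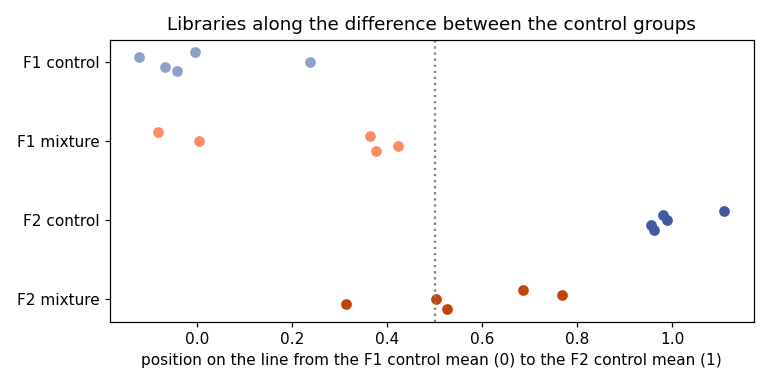
Position of each library on the line from the mean of the F1 control libraries (0) to the mean of the F2 control libraries (1). F1 mixture libraries lie between -0.0823 and 0.424 and F2 mixture libraries between 0.313 and 0.768.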

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

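Tests chosen only after the result was seen were the splits for the F1 count, the exchange of mixture libraries between generations, the overlap of genes listed at 0, the spread of the change in correlation, the joint and list splits that part all numbered pairs, the batch shared by the control libraries, and the erythrocyte covariate and removal of the length trend with their combinations with the library number as a block.

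Single libraries lay far from the other 4 of their group in 32 of 349 groups of values tested (9.17%), where chance gives about 1 in 20. F2 mixture 2 did so in 8 genes, with scaled FPKM of 0 in ccdc152, 0 in rec114, 147 in snrnp70, 4.28 in ahr, 12.3 in cyp1a1, 1.57 in gck, 7.05 in gclm and 7.17 in hsd17b11. F1 control 3 did so in 6, with 4.28 in emilin1, 41.2 in mdh2, 7.07 in manf, 92.5 in ttr, 1697 in ahsg and 385 in snrnp70. F2 mixture 1 stood apart with 0 in mitd1, 37.0 in sdc4, 1.64 in dnmt1 and 3.68 in ghr, and F1 mixture 8 with 4.39 in dnmt1, 3.26 in g6pc.1 and 53.8 in gck. The others were 2.73 in cyp7a1 (F1 mixture 4), 13.2 in nqo1 (F1 mixture 13), 4.76 in nags (F1 mixture 9), 253 in cat.2 (F1 mixture 1), 0 in mitd1 and 30.4 in c6.1 (F1 control 2), and 8.91 in irs2 and 11.7 in dhrs3 (F2 control 3). The summed FPKM was 1248690 in F2 control 1 and 943545 in F2 mixture 4, and F1 mixture 13 had 9324 genes at an FPKM of 1 or more.

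The mixture effect differed between the generations in 2052 genes and in 73 of the 120 named ones. Many named genes were picked on their fold changes or p values in these same libraries, so a high share among them is built in. The difference (F2 minus F1, log2) was negative for slc51b (-3.78), otop2 (-3.72), tmem97 (-3.53), cyp8b1.1 (-3.40), pon2 (-3.36), sdc4 (-3.15), apln (-3.13), rfk (-2.48), gm2a (-2.44), igf1 (-2.32), rpl7 (-2.21), epha2 (-1.71), prcp (-1.08) and emilin1 (-1.07). Secreted proteins with a negative difference were fgb (-2.45), serpind1 (-2.31), serpinc1 (-1.97), ahsg (-1.92), c6.1 (-1.92), tf (-1.90) and gc (-1.70). In lipid, sugar and amino acid metabolism it was negative for mttp.1 (-1.97), mat1a (-1.82), bdh1 (-1.67), ugp2 (-1.47), elovl1 (-1.18), cpt2 (-1.15), me1 (-1.06), apoe (-1.04), acadl (-0.99) and got2 (-0.93), and in mitochondrial genes for uqcrc2 (-1.74), mdh2 (-1.58), atp5f1c (-1.47), sucla2 (-1.38), suclg2 (-1.37), aco1 (-0.82) and idh3a (-0.72). In genes of the aryl hydrocarbon receptor list it was negative for cyp1a1 (-1.43), ugt1a1 (-1.06) and ahr (-0.90), and in the proteasome list for psme3 (-0.83). In retinoid, steroid, iron, redox and lysosome genes it was negative for slc40a1 (-2.07), aldh1a1 (-2.02), ctsh (-1.74), dhrs3 (-1.65), cat.2 (-1.61), ctsd (-1.47), hsd17b8 (-1.45), hjv (-1.39), gclm (-1.19), nfe2l2 (-0.91), hsd17b11 (-0.90), atg12 (-0.81) and nr3c2 (-0.64). It was positive for uroc1 (3.93), snrnp70 (3.0), tubz1 (2.98), mab21l3 (2.36), rgp1 (2.30), arntl (1.85), per1 (1.84), ezh1 (1.56), cry2 (1.5), per3 (1.49), sesn3 (1.45), mbd1 (1.39), uckl1 (1.34), ndufv1 (1.19), ep300 (1.02) and setdb1 (0.96). For rec114 (adjusted p = 0.00707) and mitd1 (adjusted p = 0.0322), listed at 0 in all F2 control libraries, no size is given.

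The F2 count of 2630 genes was reached in 1 of 100 splits of the 10 F2 libraries drawn of 126, the real one. The highest other, 1334, set F2 mixture 2 with F2 controls 2 to 5 against the rest. These splits leave aside the pairing that the library numbers were taken to show, so they do not exclude chance. The 16 splits that part all numbered pairs are too few for a share under 0.05, so they cannot exclude it either. Among them the highest other gave 8. With the library number as a block, 1773 genes were called with the mean of the erythrocyte list as a covariate and 2820 with the length trend removed, which argues against a red blood cell share or a length trend as the whole cause. A batch shared by the control libraries of both generations would move both comparisons alike, yet the fold changes correlated at -0.219 (jackknife SE 0.154). This lies below 0 by more than 1 SE, but 29 of 100 joint splits gave a correlation at least as far from 0. Such a batch therefore cannot be told apart from the group. A batch of the F2 control libraries alone is confounded with the group, and the treatment of the founders, which the design names, stays open and untested beside it.

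The fold changes of the generations went in opposite directions, with r = -0.219, but 29 of 100 joint splits gave a correlation at least as far from 0 (highest other 0.405), so chance is not excluded. Removing the length trend gave r = -0.241, a change of -0.0224 (jackknife SE 0.0325) where a rise of 0.119 was needed to reach the limit of -0.1, which argues against it as the whole cause, while the erythrocyte covariate gave -0.108, a change of 0.111 (SE 0.0784) that spans that limit, so a red blood cell share cannot be told apart from the pattern. For an exchange of mixture libraries between generations, F1 mixture libraries past the midpoint between the control groups were counted, and 0 were. F2 mixture 4 (at 0.313) lay on the F1 side, below F1 mixture 4 (0.364), 9 (0.424) and 13 (0.377). An exchange among these would put no F1 mixture library past the midpoint, so the test cannot decide on it. An exchange of control libraries, which define that line, is not addressed by this test. A biological difference between the generations stays open and untested.

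In 50 genes every library was either at 2 or more scaled FPKM or under 0.2, with at least 2 libraries on each side, and 7 of them were called in F2. Of the 50, 39 (78.0%) overlap another annotated gene, against 1015 of all 10228 tested genes (9.92%; Fisher's exact test, two-sided, p = 4.84e-30), so reads assigned to the neighbour in some libraries may account for many of them. Of 12 such genes off in all F2 control libraries 9 had an estimate in the authors' deposited table, 7 of these at a mean of 2 or more and 0 under 0.2. A sequence variant of the animals, which would also remove reads, was not tested.

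Other counts were set against splits of the libraries as well. As the real F1 count was 0, all 100 splits had to reach it, which says nothing of chance. The highest split, with 1640 genes, exchanged only F1 mixture 1 and F1 control 3, and an exchange of their labels is not excluded. The 2052 genes of the difference were reached in 1 of 100 joint splits, the real one (highest other 1706). Lists past the threshold numbered 10 in F1, reached in 51 of 100 splits (highest other 19), 1 in F2, reached in 96 (23), and 7 for the difference, reached in 83 (21), so chance is not excluded for the list counts. With splits of F2 that part all numbered pairs it is not excluded either, as 14 of 16 gave at least 1 list in F2 (highest other 18) and 58 of 100 joint splits at least 7 for the difference. Of these joint splits 26 gave a correlation of fold changes at least as far from 0, and 1, the real one, reached the 2052 genes. Among those with another F2 part the highest count of genes was 1.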

How the results depend on the processing

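Alternatives chosen only after seeing the data were keeping FAIL values, the erythrocyte covariate, removal of the length trend, the threshold of 0.10 and the combinations with the block. All 2630 genes called in F2, where tested, kept their sign in every alternative, with 1773 to 3604 calls except for 1486 at a mean FPKM of 5 or more, where fewer genes were tested and 1451 of 1466 calls remained. Leaving out 1 library gave 1774 (without F2 mixture 4) to 3287 (without F2 mixture 2). The F1 count was 0 in the main test, 4 with no filter, 3 without scaling, 1 after quantile normalization, 1129 with arrayWeights, 2 with the length trend removed, 10 at a threshold of 0.10 and 0 to 24 without 1 library (24 without F1 mixture 8). F1 numbers 1 and 4 deviated at -0.0167 and -0.187 and were not taken as pairs; with the number as a block, where these 4 libraries carry the comparison, F1 gave 19. The F2 block gave 2793 and, beyond the calls named with it in the report, changed no other call of a named F2 gene. The difference gave 1358 at a mean FPKM of 5 or more, 3864 with arrayWeights and 1380 to 2750 without 1 library. Genes called in both generations numbered 1 without scaling, 45 with arrayWeights and 0 to 1 without 1 library (1 without F1 mixture 8, F1 control 3 or F1 control 4). Lists in F1 numbered 7 after quantile normalization, 8 to 11 without 1 library, 0 with an estimated correlation and 0 by fry. Lists in F2 numbered 6 without scaling, 3 after quantile normalization, 2 with the block, 0 with an estimated correlation, 8 by fry and 0 (without F2 mixture 2) to 9 (without F2 control 2) without 1 library, 2 without F2 mixture 1, F2 mixture 4, F2 control 1 or F2 control 5. Lists of the difference numbered 0 with an estimated correlation and 4 (without F2 mixture 2) to 9 without 1 library. Of 89 named calls 78 passed in every alternative in which they were tested, and 0 of 163 named results reversed. Kept signs, here and for the 2630 genes, say little, as called genes were picked on the same libraries. The fit of 1 generation alone and the F2 block also leave the fold change of a gene with all values unchanged. Where a count moved, the cause was not tested unless named. The correlation of fold changes stayed between -0.290 and -0.108. At the depth of these libraries the median half-width of the deposited interval at an FPKM of 5 to 20 was 7.92% to 10.97%. The simulated data, with 200 changed genes of higher level, gave 13.4% recovery at 1.5-fold. Where few genes change, many changes of that size would thus be missed. In F2, where many more genes were called, the adjusted threshold is less strict, so that share does not give the recovery there.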

Other observations

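The tests in this part were chosen only after the result was seen, except the gene lists. In F2 the remaining lists moved both ways, and for each the counts that rose and fell are followed by those adjusted over the list alone. They were 0 and 4 of 28 for phase I and II detoxification (0 and 4), 0 and 2 of 23 for cholesterol synthesis (0 and 1), 1 and 1 of 18 for bile acids (0 and 1), 1 and 2 of 23 for gluconeogenesis (1 and 2), 2 and 4 of 26 for glycolysis (2 and 4), and 2 and 3 of 51 for oxidative phosphorylation (1 and 2). Protein care gave 3 and 1 of 35 for the proteasome (3 and 0), 2 and 4 of 32 for the unfolded protein response (2 and 3) and 3 and 3 of 25 for heat shock (3 and 5). Defence and growth gave 0 and 1 of 25 for complement (0 and 0), 2 and 4 of 18 for the acute phase (2 and 4), 0 and 4 of 21 for interferon (0 and 4), 3 and 1 of 17 for the cell cycle (3 and 1), 1 and 3 of 21 for p53 (1 and 3), 0 and 1 of 18 for hypoxia (0 and 0) and 3 and 3 of 23 for the extracellular matrix (3 and 3). Where camera, median and mean of a list differed in sign in F2 (bile acids, insulin and IGF signalling, cell cycle, p53, extracellular matrix), the list did not pass.

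None of the marker lists of other cell types passed camera or fry in F2 (smallest adjusted p 0.312 and 0.0665, cholangiocytes), but endothelium (0.0224) and stellate cells (0.000821) passed fry's test for change in either direction, as did 30 of all 40 lists. The counts that rose and fell were 0 and 1 of 16 for erythrocytes (0 and 0 adjusted over the list alone), 0 and 1 of 12 for macrophages (0 and 0), 0 and 1 of 8 for granulocytes (0 and 1), 1 and 0 of 8 for lymphocytes (0 and 0), 1 and 2 of 6 for endothelium (1 and 3), 2 and 2 of 10 for stellate cells (2 and 2) and 0 and 1 of 7 for cholangiocytes (0 and 0). Too few members were measured to test melanophores (3), pancreatic acinar cells (3), oocyte and ovary (1), skeletal muscle (3), gut and gallbladder (4) and mitochondrially encoded genes (2).

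Across generations the F2 control livers stood farthest from the rest. Between F2 and F1 control livers 5722 genes were called, between F2 control and F1 mixture 4692, between F2 mixture and F1 control 3122, and between F2 mixture and F1 mixture 1450. Over all genes the median size of the log2 difference was 0.61 between the control groups and 0.31 between the mixture groups. Over the 2630 genes called in F2 it was 0.96 and 0.26. These genes were picked on the F2 control and F2 mixture libraries together, which raises the value of 0.96 and can move that of 0.26. Generations can also differ in when the frogs were raised and sequenced.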
